A study of Homo sapiens with 6 samples.

How the data were processed

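Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in human umbilical vein endothelial cells (HUVECs). Per the labels' protocols, the cells were infected at about 70% confluency with an adenovirus carrying SREBP2 (Ad-SREBP2) or an empty vector (Ad-null), and nuclei of about 5000 cells were transposed after 72 h. The series title names the insert as SREBP2(N), the N-terminal form of the protein. The labels list 3 libraries per group, while the design text speaks of biological duplicates, and all 6 libraries were used. Nothing says whether the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

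Per the submitters' processing notes, bcl2fastq, Bowtie2, SAMtools, Picard, bedtools and MACS2 were used with the GRCh38 assembly, with no role, order or version given. Shifting of reads for the Tn5 offset, duplicate removal and removal of mitochondrial reads are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called on each library and not on pooled libraries. Each deposited row holds an interval, a summit, a fold enrichment (a ratio of the summit to its local background), −log10 p and −log10 q as the authors' peak caller gave them, and a whole-number score that is 10 times −log10 p with the decimals dropped. The lowest deposited −log10 p was 2.00 in every list, so the lists reach down to weak peaks. These values are the authors' own and were used only to describe, rank or filter peaks within a list. Read depths were not given; the deposited lists are the starting point here.

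Chromosomes 1 to 22 and X were kept. Of 1281840 summit rows, 1117 (0.0871%) lay elsewhere and were left out. Summits that shared an interval were counted as 1 distinct peak with the values of the most significant summit. The 6 lists were merged with bedtools 2.31.1 into union regions (overlap of at least 1 bp), and a region was present in a library that had a peak overlapping it by at least 1 bp. Regions present in all 3 Ad-SREBP2 and no Ad-null libraries are called Ad-SREBP2-only, and the reverse Ad-null-only. Because a longer list holds more such regions, the same counts were made after each list was reduced to its 152128 most significant peaks, the length of the shortest list. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.

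Gene positions came from the RefSeq gene table for GRCh38.p14, the assembly of the peak lists, with 19974 protein-coding genes on the kept chromosomes. The table gives the start and end of each gene and neither strand nor exons. The planned promoter window of 1 kb around a transcription start was therefore replaced by 1 kb around either annotated gene end, which also takes in 3′ ends, and the planned count over SREBF2 exons by a count over the SREBF2 gene span. The planned tests of 23 motifs and of sterol response elements need a genome sequence, were not run, and have no values here. All 332 symbols of the 18 gene lists fixed in advance matched the table, 1 of them through a synonym.

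Values per library were compared with an exact two-sided permutation test of the difference of group means; with 3 libraries against 3 its smallest p is 0.1, so no such comparison could reach 0.05. Single regions were not tested for the same reason. The share of regions near gene ends was compared by Fisher's exact test with regions present in exactly 3 libraries of mixed groups. Each gene list was tested by Fisher's exact test for genes with an Ad-SREBP2-only region within 10 kb of a gene end, with Benjamini-Hochberg adjustment over the 18 lists, against genes with a region present in at least 3 libraries within that distance. Regions and genes are not replicates, so these tests describe these libraries.

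The summit pileup, the number of fragments the caller saw at a summit, was recovered from the deposited fold and −log10 p, which together fix a Poisson tail. A whole number was recovered (−log10 p within 0.01) for at least 99.9996% of the summits with −log10 p under 100 in each library, and for 24 of the 24 stronger summits in SREBF2 and HBB (pileup within 0.05 of a whole number).

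The region counts were tested on simulated lists, in which every peak was moved to a random position and 200 regions were planted per direction: 183 planted Ad-SREBP2-only regions (91.5%) and 170 planted Ad-null-only regions (85.0%) were recovered. Each planted region was put in every library of its group, so losses came from chance overlap alone. Failure to call a weak site was not simulated. Peaks at random positions alone gave 587 and 165 such regions in that simulation. In simulated gene lists of 20 genes, with p multiplied by the 18 lists, 100 of 100 with 5 members near a region were called and 0 of 100 with 2, 3 or 4. That p depends only on how many members lie near a region. Lists with the same number therefore share the same outcome and do not measure a rate. Of 100 random lists, 2 had an unadjusted p under 0.05.

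The tests, the gene lists, the alternatives named at the end as fixed in advance and the rule for the genes named in the text were fixed before the data were examined. The rule for named genes took SREBF2; for each list up to 4 members with an Ad-SREBP2-only region within 1 kb, then 10 kb, and up to 2 with an Ad-null-only region, or else its first 2 members; the 10 regions of each direction with the highest value of their lowest −log10 q; and the 5 genes with the most Ad-SREBP2-only regions. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Alternatives fixed in advance were a −log10 q of at least 5, presence only where peaks cover 50% of a region, fixed 500 bp windows, lists of 50000 peaks, lists of equal length, a 500 bp gene-end window, a 50 kb gene window, 10000 matched random gene lists, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were a q of at most 0.05, a −log10 p of at least 4, 5, 10 or 20, leaving out both libraries numbered 3, leaving out 1 library at these thresholds or both libraries numbered 3 at a q of at most 0.05, and the whole gene span with 10 kb on each side. All alternatives for the SREBF2 intervals, and lists of equal length for the named regions, were also chosen after seeing the data.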

Results

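HUVECs, primary endothelial cells of the umbilical vein, carried either extra SREBP2, the transcription factor that turns on cholesterol synthesis and uptake genes, or an empty vector, with 3 ATAC-seq libraries in each group. The comparison asks where chromatin accessibility differed after 72 h of SREBP2(N) overexpression. The Ad-null lists held 152128, 166624 and 184540 distinct peaks and the Ad-SREBP2 lists 229476, 267939 and 242601. Read depth was not given, and the background pileup recovered from the lists was 1.30, 0.892 and 0.989 fragments in the Ad-null and 1.09, 1.19 and 1.045 fragments in the Ad-SREBP2 libraries.

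The SREBF2 gene, which encodes SREBP2, held the strongest peaks of every Ad-SREBP2 list. SREBF2 spans positions 41833105 to 41907305 of chromosome 22 (GRCh38), and 5 intervals inside it were present in all 3 Ad-SREBP2 and no Ad-null libraries. Their summit pileups were 3645 ± 1783 fragments at 41866759 to 41867350, 2356 ± 1090 at 41868547 to 41868864, 2364 ± 1231 at 41870817 to 41871089, 2560 ± 1114 at 41873727 to 41874089 and 1621 ± 635 at 41875264 to 41875790 (mean ± SD, n = 3). No peak overlapping SREBF2 in an Ad-null library had a pileup above 17. The highest SREBF2 pileup was 5.10, 3.23 and 6.32 times the highest pileup outside SREBF2 and HBB in Ad-SREBP2 libraries 1, 2 and 3. That highest pileup lay over pseudogenes of mitochondrial sequence on chromosome 1 (633915 to 634867 in library 3), and 8 of the 20 strongest peaks in each Ad-SREBP2 list and 10, 11 and 12 in the Ad-null lists lay over such pseudogenes. A further summit near the start of the gene, at 41833333 in Ad-SREBP2 libraries 1 and 2 and at 41833332 in library 3, reached 190, 121 and 354 fragments. Peaks overlapping this gene start in the Ad-null libraries had highest pileups of 16, 16 and 17. Sequence of the SREBP2 insert of the virus is also sequence of this gene, so peaks here do not separate vector from chromatin.

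**Figure D1:**
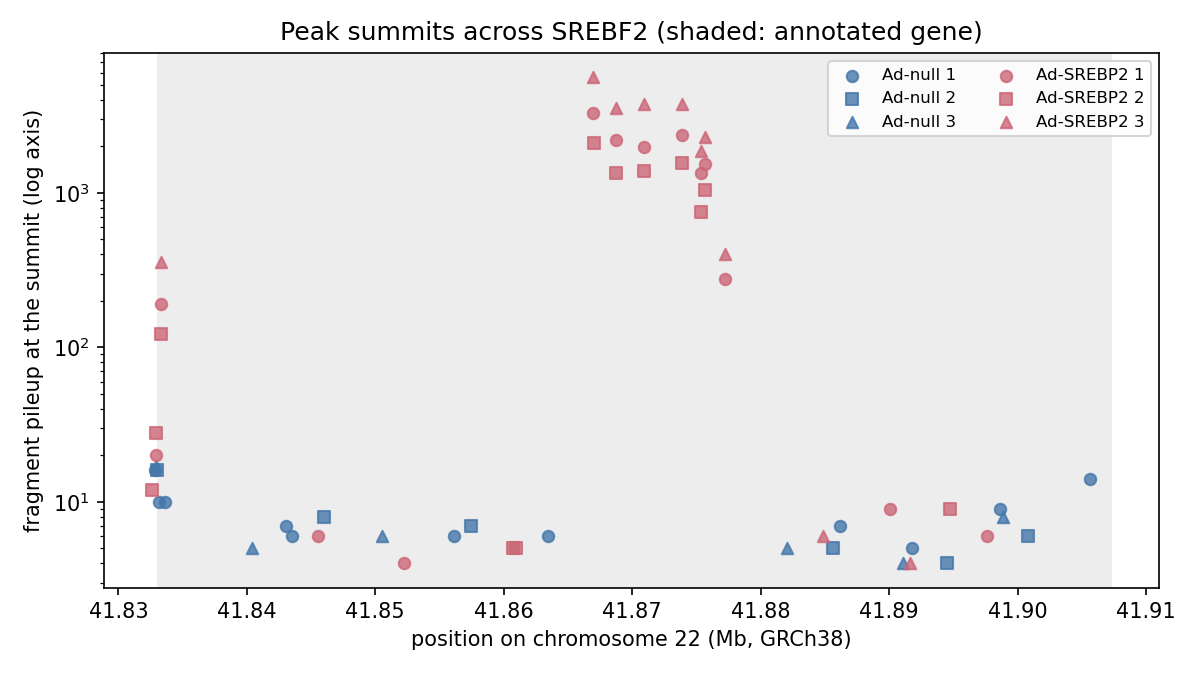
Fragment pileup (log axis) at each peak summit against position on chromosome 22 (Mb, GRCh38), 1 colour per group and 1 symbol per library, with the annotated SREBF2 gene shaded. The 5 Ad-SREBP2-only intervals lie between 41866759 and 41875790, where Ad-null libraries have no peak, and the summits of Ad-null libraries reach at most 17.

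HBB, the adult beta-globin gene of red cells, held the other very strong interval. It lay at 5226768 to 5227025 of chromosome 11, inside the gene (5225464 to 5227071), with the same start and end in all 3 Ad-SREBP2 libraries and a pileup of 790 ± 290 fragments (SD, n = 3). This was 1.29, 0.750 and 1.20 times the highest pileup outside SREBF2 and HBB in Ad-SREBP2 libraries 1, 2 and 3, and 2.24, 1.30 and 1.82 times the highest one that also lay outside mitochondrial pseudogenes. No Ad-null library had a peak overlapping HBB, and 1 had a peak within 1 kb of its ends. After these 6 intervals the strongest Ad-SREBP2-only regions were far weaker. A region at 89836248 to 89836596 of chromosome 2, 522723 bp from the nearest protein-coding gene, had a lowest −log10 q of 9.91 over its 3 libraries. Regions nearest PAGE3 (4.19), in FSTL4, which encodes a follistatin-like protein (4.13), and nearest SH2D4B (3.53) followed.

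The Ad-SREBP2 lists were longer in all 3 libraries. They held 246672 ± 19552 distinct peaks against 167764 ± 16236 (SD, n = 3 each), a ratio of 1.47 (exact permutation p = 0.1, two-sided, the smallest this design allows). Peaks covered 58.0 ± 4.81 Mb in Ad-SREBP2 and 39.6 ± 1.35 Mb in Ad-null libraries (SD, n = 3 each; exact permutation p = 0.1). Median widths were 193 ± 1.53 bp and 194 ± 12.5 bp, which differed by less than the spread between libraries (exact permutation p = 1, n = 3 each). At a −log10 p of at least 4, a threshold added after the data were examined, means were 57145 in Ad-null and 61130 in Ad-SREBP2 libraries, a ratio of 1.07, and the groups overlapped (exact permutation p = 0.7, n = 3 each). At 5, 10 and 20 the ratios were 1.12, 1.46 and 2.33, again with overlapping groups (exact permutation p = 0.8, 0.5 and 0.4, n = 3 each), and without Ad-SREBP2 library 3 the difference turned to −2647 peaks at 4 and −1874 at 5, and the ratios at 10 and 20 were 1.04 and 1.14. Among peaks with q of at most 0.05, the Ad-SREBP2 libraries held 49007, 63642 and 119850 and the Ad-null libraries 65404, 62241 and 36180, and the groups overlapped (exact permutation p = 0.5, n = 3 each). These thresholds were added later too.

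**Figure D2:**
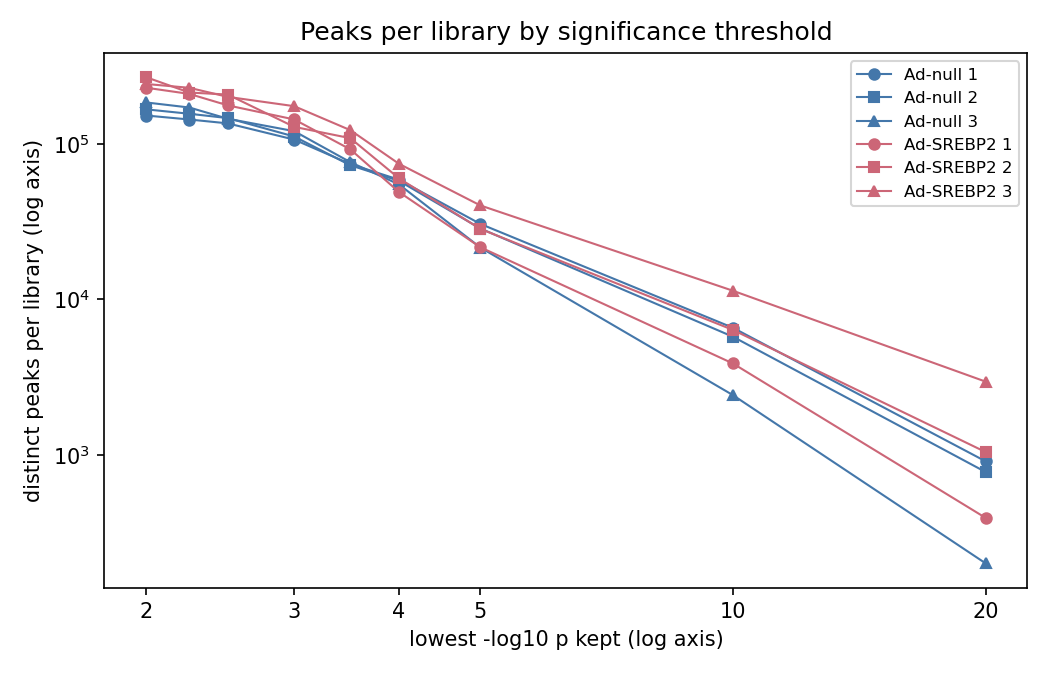
Distinct peaks per library (log axis) against the lowest −log10 p kept (log axis), with 1 line per library. All 3 Ad-SREBP2 libraries lie above all 3 Ad-null libraries up to a −log10 p of 3.5, and the groups overlap from 4 upward.

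Merging the lists gave 952061 regions, of which 809663 (85.0%) were in a single library and 14423 in all 6. Regions shared by all 6 libraries lay mostly at genes: 53.3% were within 1 kb of a gene end, against 2.92% of those in 1 library. Covered bases shared between 2 libraries made up 9.54% of their joint length within Ad-SREBP2, 10.4% within Ad-null and 9.76% between the groups, as means over 3, 3 and 9 pairs. Both within-group means lay inside the range over pairs of different groups, 7.13% to 12.7%.

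Ad-SREBP2-only regions numbered 1861 and Ad-null-only regions 525. From lists of equal length the counts were 807 and 587. Most were weak: 206 of the 1861 (11.1%) and 33 of the 525 (6.29%) had a q of at most 0.05 in each of their 3 libraries, against 59.6% of the regions in all 6. Regions found in all 6 libraries are stronger by selection, so this contrast says nothing particular about regions of 1 group. Peaks moved to random positions gave 523 ± 17.6 Ad-SREBP2-only and 170 ± 16.9 Ad-null-only regions (SD over 5 placements). These placements kept the list lengths but not the sites that libraries share. At most 1 region of a placement lay in all 6 libraries, against 14423 in the data. The strongest Ad-null-only regions lay in SEPTIN11, which encodes a cytoskeletal GTPase (lowest −log10 q 2.48), in MAST4, a kinase gene (2.27), nearest CBLC (2.26), in SMARCD3, which encodes a subunit of a chromatin remodelling complex (2.06), and in COL18A1, which encodes the collagen that yields endostatin (1.92). AP1S2 (1.88), PTPRR (1.71), RPS23 (1.70) and an uncharacterised gene (1.65) were nearest to 4 more. The 5 protein-coding genes taken as having the most Ad-SREBP2-only regions within 10 kb of a gene end had 2 each. This window leaves out the intervals deep inside SREBF2. The genes were ACOXL, ASB9, BCL2L11, which encodes a pro-apoptotic protein, CAMKK1, a kinase gene, and HOXB3, a homeobox gene. They stand in alphabetical order, so further genes with 2 may have been cut at a tie. ACOXL ends at 111118548 and BCL2L11 starts at 111120914 of chromosome 2, so both may count the same regions. No region was tested alone, since an exact test of 3 libraries against 3 cannot go under 0.1.

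**Figure D3:**
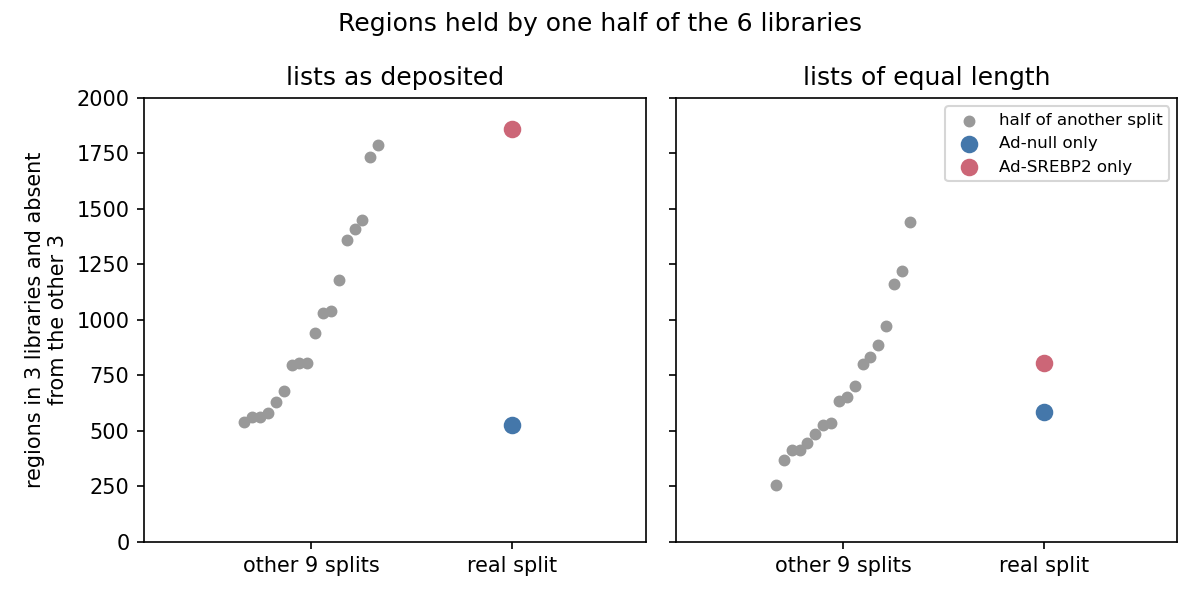
Number of regions present in 3 libraries and absent from the other 3, for the real groups (coloured) and for both sides of the other 9 splits of the 6 libraries (grey), from lists as deposited (left) and lists of equal length (right). As deposited, 1861 Ad-SREBP2-only regions lie above the highest other value of 1790; with equal lengths, 807 lies below the highest other value of 1440.

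Ad-SREBP2-only regions lay less often near gene ends than regions in 3 libraries of mixed groups: 136 of 1861 (7.31%) against 1713 of 17911 (9.56%), an odds ratio of 0.746 (Fisher's exact p = 0.00126). Of the Ad-null-only regions 54 of 525 (10.3%) lay there (odds ratio 1.08, Fisher's exact p = 0.548). The Ad-SREBP2 odds ratio was 0.916 at a −log10 q of at least 5, 0.872 at a q of at most 0.05 and 0.920 without Ad-SREBP2 library 1, and passed the threshold in none of these (Fisher's exact p = 0.555, 0.261 and 0.0609). It was 0.745 from lists of equal length and 0.748 with fixed 500 bp windows (Fisher's exact p = 0.0193 and 2.71e-05). Where peaks had to cover 50% of a region it was 0.784 (Fisher's exact p = 0.0029). The test is over regions of these libraries, and 1 of the other 9 splits of the 6 libraries, which mixed the groups, gave a larger deviation (absolute natural log of the odds ratio 0.340, against 0.294).

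At the level of genes, 9616 of 19974 protein-coding genes had a peak within 1 kb of a gene end in all 6 libraries, 143 in all 3 Ad-SREBP2 and no Ad-null libraries, and 40 in the reverse. From lists of equal length the last 2 counts were 65 and 77, so the direction turned. Among stronger peaks they were 112 and 2 at a −log10 q of at least 5 and 94 and 16 at a q of at most 0.05. These stronger lists were not cut to equal length. At a −log10 q of at least 5 they held 3486 to 9537 Ad-null and 5619 to 16072 Ad-SREBP2 peaks. Cut to equal length at the same 2 thresholds, they gave 73 against 67 and 375 against 167 regions. BMP6, a growth factor gene of the BMP family, was among the 143 and stayed at 3 against 0 libraries with equal lengths, as did the keratin gene KRT5, chosen after its values were seen. THY1, a fibroblast surface marker also chosen after its values were seen, had a peak in 3 Ad-null and 0 Ad-SREBP2 libraries (2 and 0 with equal lengths).

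Cholesterol synthesis genes were accessible in both groups. Of 21 members 16 had a gene-end peak in all 3 Ad-null and 19 in all 3 Ad-SREBP2 libraries (16 and 17 with equal lengths). FDFT1, which encodes squalene synthase, had 1 against 3 libraries and an Ad-SREBP2-only region at 11794476 to 11794784 of chromosome 8 (lowest −log10 q 0.341), and with lists of equal length it had 1 against 1. Among sterol uptake and regulation genes, 13 of 16 had peaks in all 3 Ad-null and 15 in all 3 Ad-SREBP2 libraries. In fatty acid synthesis the count was 8 of 12 in both groups, with ACLY and ACACA at 3 against 3. Of these 3 lists, FDFT1 alone lay within 10 kb of an Ad-SREBP2-only region.

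IL1B, the interleukin-1 beta gene, had an Ad-SREBP2-only region inside the gene, at 112831658 to 112832138 of chromosome 2 (lowest −log10 q 1.01), which was no longer Ad-SREBP2-only at a q of at most 0.05 or where peaks had to cover 50% of it. It belongs to an NLRP3 inflammasome and NADPH oxidase list of which 3 of 17 members in Ad-null and 4 in Ad-SREBP2 had gene-end peaks in all 3 libraries. At its gene ends IL1B had peaks in 2 Ad-null libraries and 1 Ad-SREBP2 library (1 and 0 with equal lengths). In endothelial inflammatory activation the counts were 12 and 13 of 20 (12 and 11 with equal lengths, so the direction turned), with the adhesion genes VCAM1 at 0 against 2 and ICAM1 at 3 against 3 libraries. TGF-beta and BMP signalling had 16 and 21 of 24 members (15 and 18 with equal lengths), and regions near BMP6 (chromosome 6, 7725834 to 7726319, lowest −log10 q 1.63) and SMAD4 (1.19). Wnt signalling had 16 and 17 of 25, an Ad-SREBP2-only region at WNT2B (2.67) and an Ad-null-only one at PORCN (0.772). PORCN still had gene-end peaks in 3 Ad-null and 3 Ad-SREBP2 libraries, also with equal lengths. Mesenchymal genes had 11 and 13 of 22, and 11 and 10 with equal lengths, so the direction turned. ACTA2 had 3 against 3 and TAGLN 1 against 3 libraries (3 against 2 and 1 against 2 with equal lengths).

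Endothelial identity genes had gene-end peaks in all 3 libraries for 11 of 27 members in Ad-null and 14 in Ad-SREBP2 (11 and 12 with equal lengths). SOX17, an endothelial transcription factor gene, had an Ad-SREBP2-only region at 54457917 to 54458261 of chromosome 8 (lowest −log10 q 0.614), and TEK, the angiopoietin receptor gene, an Ad-null-only region (1.36). Interferon response genes had 11 and 17 of 22 (11 and 14 with equal lengths). ISG15 stood at 3 against 3 libraries and IFIT1 at 2 against 3, or 2 against 2 with equal lengths. The counts were 14 and 13 of 16 for p53 and DNA damage, with a region near BBC3 (0.699), 18 and 19 of 20 for cell cycle, with one near E2F1 (0.697), and 13 and 13 of 16 for the unfolded protein response, with HSPA5 and HSP90B1 at 3 against 3. At its gene ends BBC3 had peaks in 3 Ad-null and 2 Ad-SREBP2 libraries (3 and 1 with equal lengths).

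Lists of other cell types and controls were treated alike. Leukocyte markers had 2 and 5 of 16 (2 and 1 with equal lengths, so the direction turned), with an Ad-SREBP2-only region near CSF1R (0.661) and an Ad-null-only one near CD4 (0.579). Smooth muscle and fibroblast markers had 3 and 3 of 14, with MYH11 at 2 against 0 and MYOCD at 2 against 3 libraries. Epithelial markers had 2 and 3 of 12, with EPCAM at 2 against 3 and CDH1 at 1 against 2, and neuronal genes 5 and 4 of 16, with an Ad-SREBP2-only region near GRIN1 (1.02). At its gene ends GRIN1 had peaks in 2 Ad-null libraries and 1 Ad-SREBP2 library (2 and 0 with equal lengths). Housekeeping genes, with ACTB and GAPDH at 3 against 3 libraries, had 13 and 15 of 16, against 53.2% and 58.9% of all protein-coding genes.

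From lists of equal length the counts were also 3 and 3 for the NLRP3 list, 15 and 15 for Wnt signalling, 1 and 3 for smooth muscle and fibroblast markers and 3 and 3 for neuronal genes. They were 12 and 13 for sterol uptake and regulation, 8 and 8 for fatty acid synthesis, 14 and 13 for p53 and DNA damage, 17 and 18 for cell cycle, 13 and 13 for the unfolded protein response, 2 and 3 for epithelial markers and 13 and 15 for housekeeping genes. The regions near FDFT1, SOX17, E2F1 and CSF1R were no longer in all 3 Ad-SREBP2 libraries and no Ad-null library. At a q of at most 0.05 this class was also lost by the regions near these 4 genes and near IL1B, SMAD4, BBC3 and GRIN1, and the Ad-null-only class by those near CD4 and PORCN. Where peaks had to cover 50% of a region, the same 8 Ad-SREBP2-only regions and those near WNT2B and BMP6 lost their class, as did the Ad-null-only ones near PTPRR, COL18A1, SMARCD3, TEK and PORCN. At a −log10 q of at least 5 only 7 named regions were left, the 6 in SREBF2 and HBB and the one at 89836248 of chromosome 2.

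None of the 18 lists passed Fisher's exact test for nearness to Ad-SREBP2-only regions with Benjamini-Hochberg adjustment: the smallest adjusted p was 1 and 0 lists had an unadjusted p under 0.05 (smallest 0.242). For Ad-null-only regions the smallest unadjusted p by Fisher's exact test was 0.139, and its adjusted value 1. At most 2 members of a list lay near an Ad-SREBP2-only region, and simulated lists of 20 with 4 such members were not called either.

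**Figure D4:**
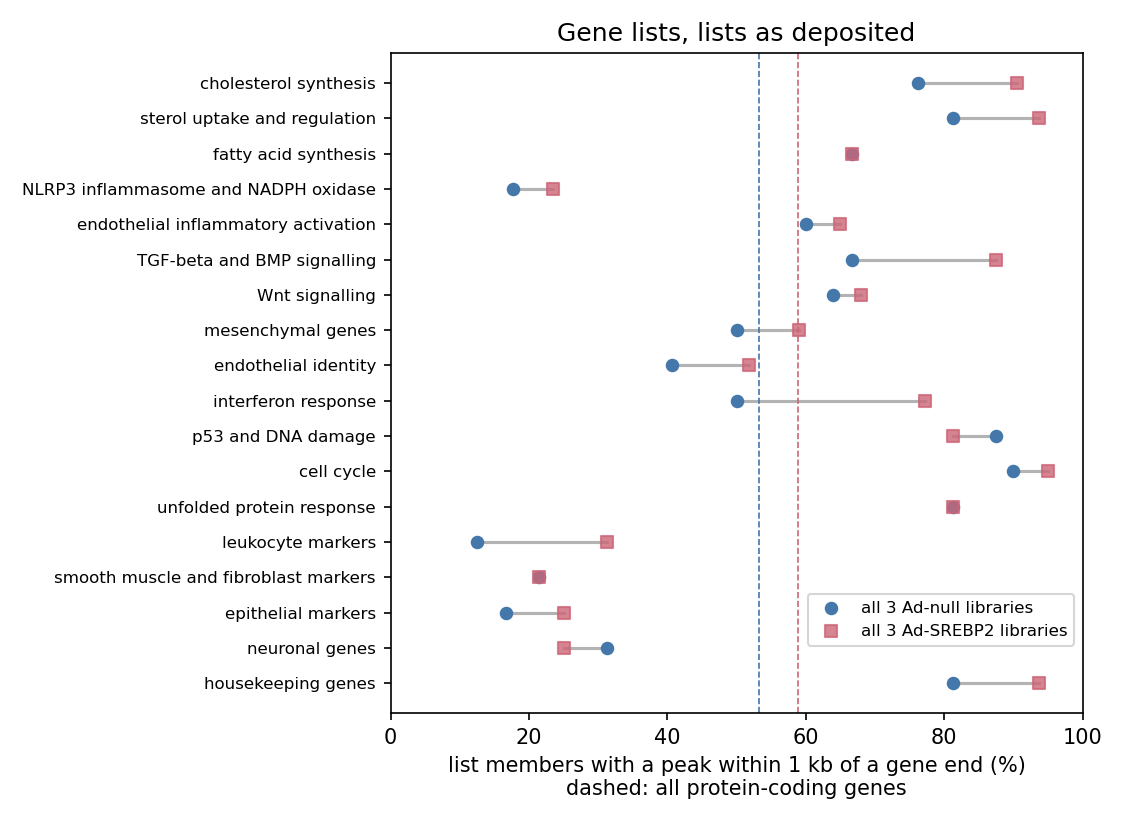
Share of each list's members (%) with a peak within 1 kb of a gene end in all 3 Ad-null (circles) and all 3 Ad-SREBP2 (squares) libraries, from lists as deposited; dashed lines mark all protein-coding genes, 53.2% and 58.9%. Cholesterol synthesis genes stand at 76.2% and 90.5%, and housekeeping genes at 81.2% and 93.8%.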

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

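The thresholds of q at most 0.05 and −log10 p at least 4, 5, 10 and 20, the gene-span window, the removal of both libraries numbered 3, all alternatives for the SREBF2 intervals and equal lengths for named regions were chosen after the data were seen. The excess of peaks and of covered length in Ad-SREBP2 kept its direction in all settings run but 3, with differences of 78908 peaks as deposited, 3985 at a −log10 p of at least 4 and 68274 to 87506 peaks without 1 library. It turned to −7498 peaks at a q of at most 0.05 without both libraries numbered 3, and without Ad-SREBP2 3 to −2647 and −1874 at a −log10 p of at least 4 and 5; no setting could give a p under 0.1. The median width difference of −0.667 bp turned to 16.3 bp at a −log10 q of at least 5 and 4.33 bp at a q of at most 0.05, and ran from −7.67 to 4.33 bp without 1 library. Pairing of libraries by number was not seen, but it cannot be excluded. Deviations of same-numbered libraries correlated at −0.00856, 0.00915 and −0.0207 over 142398 regions. Libraries of other numbers correlated at −0.0115 to 0.0195. Values this small in every pair cannot show whether same-numbered libraries shared a culture or batch. With the number as a replicate block the differences were 78908 peaks (exact sign-flip p = 0.25, the smallest possible), 18.3 Mb (0.25) and −0.667 bp (1), and no call changed.

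Ad-SREBP2-only regions numbered 199 at a −log10 q of at least 5, 597 at a q of at most 0.05, 1059 where peaks had to cover 50% of a region and 10533 without both libraries numbered 3; Ad-null-only regions numbered 13, 115, 261 and 6608. From lists of equal length these counts were 73, 375, 715 and 4421 against 67, 167, 285 and 7078, and 462 against 194 from the 50000 most significant peaks. Without 1 library they ran from 2410 to 11469 and from 719 to 4598 as deposited, and from 1084 to 4981 and from 799 to 4953 from equal lengths. They grow by construction, since a group of 2 needs fewer libraries: the Ad-SREBP2-only count was 11469, 10839 and 9465 without Ad-SREBP2 1, 2 and 3, and the Ad-null-only count 4598, 4331 and 4551 without Ad-null 1, 2 and 3. The odds ratio near gene ends was 0.916 (Fisher's exact p = 0.555) at a −log10 q of at least 5 and 0.872 (p = 0.261) at a q of at most 0.05, with fewer regions in both, and ran from 0.730 to 0.920 without 1 library, highest without Ad-SREBP2 1. Genes with Ad-SREBP2-only gene ends numbered 112 at a −log10 q of at least 5, 94 at a q of at most 0.05, 65 from equal lengths, 452 without both libraries numbered 3 and 262 to 329 without 1 library; Ad-null-only ones numbered 2 at a −log10 q of at least 5, then 16, 77, 374 and 86 to 185. No gene list passed in any setting run: the smallest adjusted p was 0.136 without Ad-SREBP2 2 and 0.708 with whole gene spans, each with 1 list at an unadjusted p under 0.05 (0.00754 and 0.0465), and 0.860 to 1 in the others. Ad-SREBP2-only intervals in SREBF2 numbered 5, and 6 without Ad-SREBP2 2. Of 33 named regions, 29 stayed in their class from equal lengths, 23 at a q of at most 0.05, 18 with 50% cover and 7 at a −log10 q of at least 5. Read depths were not given, so what depth limits was not measured. Tests of motifs and of sterol response elements, with their alternatives, were not run.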

Other observations

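The rules for weighing explanations in this part, and the counts of genes by direction, were chosen after the results were seen. Some of the counts weighed, such as those from lists of equal length, were themselves fixed in advance.

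Interferon response and TGF-beta and BMP genes each had 8 members with a gene-end peak in more Ad-SREBP2 than Ad-null libraries and 1 with the reverse, against 4436 and 2393 of all protein-coding genes (odds ratio 4.32, Fisher's exact p = 0.174, adjusted p = 1 over 18 lists). This lean was not particular to them: epithelial markers had 7 against 2, leukocyte markers 6 against 2 and cholesterol synthesis genes 4 against 0. Fatty acid synthesis (1 against 2) and p53 and DNA damage (0 against 1) leaned the other way. IFI44L, an interferon-induced gene, had 1 against 3 libraries with lists as deposited and of equal length, and CXCL10, a chemokine gene, 1 against 3 and then 1 against 1. From lists of equal length the interferon list had 3 against 2 such members, the TGF-beta and BMP list 5 against 3, and all genes 3530 against 3343. Among endothelial genes PECAM1, which encodes an endothelial adhesion molecule, had 1 against 3 libraries in both forms of the lists, and RSPO3, a Wnt activator gene, 3 against 1; these 4 genes were chosen after their values were seen.

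Among chromosomes 1 to 22, the ratio of Ad-SREBP2 to Ad-null peaks was highest on 4 (1.65) and 13 (1.62), with 4.05 and 2.96 protein-coding genes per Mb. It was lowest on 19 (1.21) and 22 (1.24), with 24.8 and 8.88. The ratio on chromosome X was not computed, so X has no place in this ranking.

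The longer Ad-SREBP2 lists have 3 candidate explanations. A higher background density was not seen in all pairs: the background pileup was higher in the Ad-SREBP2 library in 6 of 9 pairs, the other 3 all with Ad-null 1, so it cannot be told apart from the other explanations, since 1 library decides it. Pileups are whole numbers, so the chance that background reaches a fixed p moves in steps. At a −log10 p of 2.5 the Ad-SREBP2 library had the lower chance and still more peaks in 6 of 9 pairs. Those were the pairs with Ad-null 1 and 2 (176832 to 207554 against 135455 and 146469). The chance was computed at each library's background pileup only. Of summits with a −log10 p under 100, 24.0% to 32.6% in Ad-null and 39.1% to 51.9% in Ad-SREBP2 libraries lay at that background. The remaining summits had another local background, so these pairs cannot decide whether the steps are the whole cause. As part of the cause the steps cannot be told apart from the other explanations. The ratio of mean peak numbers was 1.47 at 2 and 1.45 at 3.5, where the chance is higher in all 3 Ad-SREBP2 libraries. It was 1.07 at 4, where the chance is lower in all 3. At 5, 10 and 20 the groups also overlapped, with the chance lower in the Ad-SREBP2 library in 8, 6 and 7 of 9 pairs. An opening of more sites by SREBP2 also stays open: at a q of at most 0.05 the groups overlapped, and the mean difference of 22891 peaks rested on single libraries, with 1716 without Ad-SREBP2 3, 13677 without Ad-null 3, 37138 without Ad-SREBP2 1 and −7498 without both libraries numbered 3.

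The SREBF2 and HBB peaks of the Ad-SREBP2 libraries may be vector DNA counted at matching genome sequence. Both edges of all 6 intervals lay within 10 bp over the 3 libraries, against 21 of the 200 strongest regions shared by all 6 libraries (Fisher's exact p = 3.00e-06). The 6 intervals are not independent if 1 vector is their source, and HBB was taken for its strength in these lists. The 200 regions were not matched to them on pileup, so this p does not weigh vector DNA against strong signal. Opening of the cells' own SREBF2 locus as the whole source is argued against by pileups at least 3.23 times the highest elsewhere in each library. For HBB such ratios were 1.29, 0.750 and 1.20 in Ad-SREBP2 1, 2 and 3, against a peak over mitochondrial pseudogenes in each, and 2.24, 1.30 and 1.82 against the highest outside those. With library 2 below the pseudogene peak, the test against the highest pileup cannot tell opening of that locus from vector DNA. Outside SREBF2 and such pseudogenes, the HBB pileup was the highest in all 3 Ad-SREBP2 libraries. No Ad-null library had a peak overlapping HBB. Whether the vector carries beta-globin sequence is not given in the sources used here.

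The larger number of Ad-SREBP2-only than Ad-null-only regions may follow list length in part. The ratio was 3.54 as deposited, 3.11 ± 0.321 with peaks at random positions (SD over 5 placements) and 1.37 from lists of equal length. At random positions the ratio follows from the list lengths by construction, and sites that libraries share were not kept. It therefore does not show that list length gave the ratio in the data. With equal lengths the ratio was also 1.09 at a −log10 q of at least 5, 1.29 with fixed 500 bp windows and 0.625 without both libraries numbered 3, but 2.38 from the 50000 most significant peaks and 2.51 where peaks had to cover 50% of a region, with 375 against 167 regions at a q of at most 0.05. Since these go both ways, list length cannot be told apart from an effect of SREBP2 on part of these regions, which was not tested.

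The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real value and the highest of the other splits were 1861 and 1790 for Ad-SREBP2-only regions (1 split as large, the real one included), 525 and 1790 for Ad-null-only regions (10), 807 and 1440 (7) and 587 and 1440 (10) from lists of equal length, 143 and 133 (1) and 40 and 133 (10) for genes with such gene ends, 0 and 1 (10) for gene lists, and 0.294 and 0.340 (2) for the absolute natural log of the odds ratio near gene ends. From equal lengths the highest split set Ad-null 1, Ad-null 2 and Ad-SREBP2 3 against the rest. These libraries had 43.0%, 37.4% and 49.4% of their peaks at a q of at most 0.05, against 19.6% to 23.8% in the others, a structure of the libraries that crosses the groups.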
